A study of Sus scrofa with 44 samples.

How the data were processed

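Gene expression was measured in granulosa cells, the somatic cells that line the antral follicle and surround the oocyte, of 8 multiparous sows. Per the labels, the cells of single follicles were collected by laser capture microdissection, and about 40 ng of total RNA per follicle was amplified and labelled. Each of the 44 arrays was a porcine 2-colour Agilent oligonucleotide array. The red dye, Cy5, held the RNA of 1 follicle and the green dye, Cy3, held a common reference made by pooling 32 of the samples, per the labels. No dye swap was made, so a dye effect that is specific to a probe stays in every ratio. It cancels in differences between arrays where it is the same on each of them.

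The deposited scanner files hold, per spot, intensity values: mean brightness and median local background in each channel, as read by Agilent Feature Extraction 10.7.3.1 per the submitters' processing notes. The files also hold a processed intensity for each channel that Feature Extraction had background-subtracted and normalized between the dyes, per the file headers. A deposited value table of the whole series holds the authors' processed log2 values of the same arrays for 11409 identifiers. Its values were displaced against its identifiers. A shift of 366 places gave a correlation of 0.992 between its row means and the mean log2 processed Cy5 signal of the scanner files. Any other of 1000 shifts on each side gave at most 0.0362. After that shift 11043 identifiers were used, and each column followed its own array with a median correlation of 0.889 (lowest 0.335) over values centred per probe. The slope of 0.991 against bright scanner ratios and the sign of the correlations settled its scale as log2 and its direction as rising with the sample. Whether its values are ratios to the reference or levels of the Cy5 channel was not settled. Column medians lay between 6.96 and 7, and the normalization and the origin of that centre stay unknown, so the table served only as an alternative to the scanner files.

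From the scanner files, the background was corrected with limma's normexp method (offset 50), and each array was normalized by loess within the array, with control spots at weight 0. Spots with an outlier flag were left out, between 3 and 43 per array, and saturated spots, present on 1 array, were kept. The value analysed was the log2 ratio of Cy5 over Cy3, that is of the follicle over the reference pool. Spots of the same probe were averaged, which turned 43803 spots into 43603 probes. Names came from the scanner files and, where the files gave an accession or an older name, from the reference gene tables: 7675 probes carried a current symbol, 8 an older symbol, 6702 were named through an accession and 418 through a gene number. A further 212 kept the name in the file and 28588 had no symbol and were tested under their probe identifier. A probe was used when it was well above background in Cy5 on at least 50% of the arrays of at least 1 of the 4 groups of follicle size and sow group, which left 20877 probes in and 22726 out. For the 2143 symbols with over 1 such probe, the brightest probe stood for the gene, so that 15727 features were tested, of which 4935 had a symbol.

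The replicate was the sow. Follicles of the same size and sow were averaged, which gave 16 sow-by-size means. Each of the 8 means of large follicles held 3 follicles, and of the 8 means of small follicles 4 held 3 and 4 held 2. The fifth follicle of 4 sows was not analysed here. Large and small follicles came from the same animals, so sow entered as a fixed block and the size comparison rested on 8 within-sow differences, 4 in sows with high and 4 in sows with low variation in follicle size, which share an estimate of the spread. As a check of this pairing, the deviations of the large and the small mean of a sow from their group means correlated at 0.197 to 0.689, and for 5 of the 8 sows the partner was the best match. Sows of high and low variation, and sows of high and low oocyte health, were compared on 8 sow means, 4 against 4. All fits used limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with statmod 1.5.0 and version 1.17.8 of the data.table package, and p-values were adjusted by Benjamini and Hochberg over the features of a comparison, with a threshold of 0.05. Every adjusted p of a single gene is from limma.

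The main tests, the gene lists, the rule for the genes to be named and most alternatives were chosen before the data were examined. The rule took, for large against small follicles, the 12 genes with the largest and the 12 with the smallest log2 change among those with a symbol, past the threshold and with the same sign in all 8 sows. For the other comparisons it took the 6 largest and 6 smallest changes past the threshold, or, where none passed, the 4 per direction with the smallest p, given as not passing. It added the 4 members with the smallest p of each list past its own test, and a fixed panel of granulosa, theca and other marker genes, of which 17 were measured and COL1A1 and HBB were not. Of the genes so named, 2 are not reported here. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 32 lists of a comparison that had at least 5 measured members. Beside it stand camera with an estimated correlation, the rotation test fry and an exact test of the list mean per sow, which flips the signs of within-sow differences or reassigns the sows and was added after seeing the data. Fry asks whether a list moves one way and does not set it against other genes. The lists for lymphocytes (4 measured members), erythrocytes (0) and cumulus cells (4) were too small to test.

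The limma fits were tested on simulated sow-by-size means of the 8 sows, with 15727 features and 200 changed features. Noise was normal and independent between features, without slide effects, and the steps before these means were not simulated. For the size comparison over 8 sows, 100% of changes of 2-fold and 98% of 1.5-fold were recovered with 13 false calls. In sows of high variation the shares were 99% and 96%, and in sows of low variation 100% and 91%. For the difference between these size effects they were 93% and 81%, for the comparison of sows by variation 100% and 81%, and for that by oocyte health 93% and 86%, with no change recovered in the wrong direction.

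Each slide carried 4 arrays of 4 different sows and of 1 follicle size, with 6 slides of large and 5 of small follicles. Slide was therefore a random block in an alternative of the size comparisons, and a fixed term, with sow as a random block, in one of the comparisons between sows, which were also made within each slide. The other alternatives changed the background correction, the signals, the use of the reference channel, the filter, the probe rule, the source table, the unit of replication and the sows and arrays included. The number of arrays limits the precision, and at 4 against 4 sows no exact p can be under 0.0286. A list at that floor passes the adjustment over 32 lists only if many others lie there too. Within 4 sows no exact p can be under 0.125, so the exact test could call no list there.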

Results

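Granulosa cells of single ovarian follicles were profiled in 8 sows selected from 29 that were slaughtered within 2 hours after weaning, when a new wave of follicles starts to grow. Sows had been selected by the spread in diameter of the 10 largest healthy follicles of the right ovary. In 4 HighVAR sows the SD of follicle size was 1.56 ± 0.18 mm and in 4 LowVAR sows it was 0.54 ± 0.16 mm, per the labels. From each sow the 3 largest follicles and the 3 smallest of those 10 were taken, called large and small here. The arrays numbered 12 for large and 10 for small follicles in each sow group. The same sows were also grouped by the share of healthy cumulus-oocyte complexes (COC, the oocyte with its surrounding cells), with 4 HighCOC sows above 70% and 4 LowCOC sows below it. The groupings overlap, since 3 HighVAR sows were HighCOC and 3 LowVAR sows were LowCOC. Sows are named by their number after H (HighVAR) or L (LowVAR).

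Signal in the follicle channel varied more between arrays than signal in the reference channel. The 99th percentile of Cy5 intensity over background ranged from 971 to 11940, and that of Cy3 from 3671 to 6173. Probes well above background in Cy5 made up 26.16% to 54.53% of all probes. Their mean share was 36.8% ± 6.13 (SD, n = 12 arrays) for large follicles of HighVAR sows and 41.8% ± 4.32 (n = 12) for those of LowVAR sows. For small follicles it was 44.5% ± 6.25 (n = 10) in HighVAR and 44.1% ± 8.46 (n = 10) in LowVAR sows. Large follicles were dimmer in Cy5 by -0.46 on the log2 scale (SD 0.64 over 8 sows, lower in 6 of 8), which did not pass an exact sign-flip test (two-sided p = 0.0938, adjusted p = 0.205 over 7 tests of array quality).

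**Figure D1:**
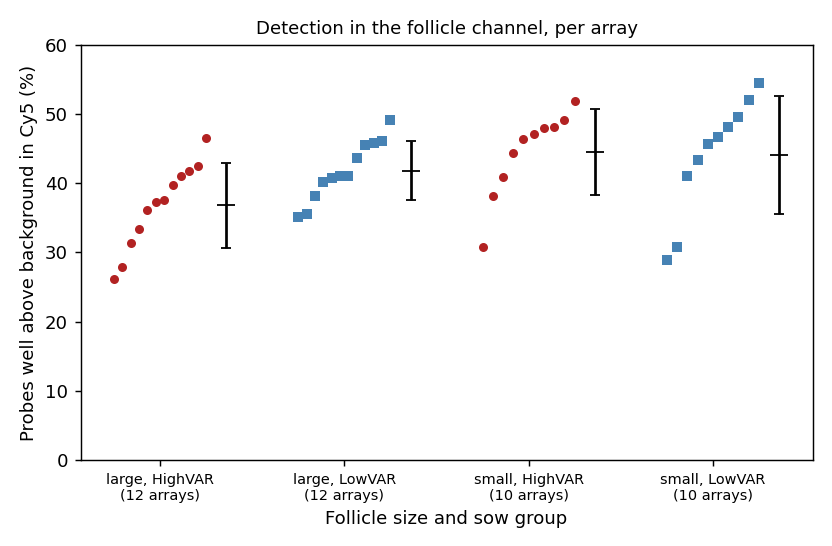
Share of probes well above background in the follicle channel (percent, y axis) for each array (points), by follicle size and sow group (x axis), with the mean and SD of each group as bars. Group means lie between 36.8% (large, HighVAR) and 44.5% (small, HighVAR), with the lowest array at 26.16% and the highest at 54.53%.

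The first comparison, which the series names as its main question, set large against small follicles. Across the 8 sows, the largest rises in large follicles were in SAT1, which acetylates polyamines (log2 change 0.95 ± 0.13 SE, 1.93-fold higher, limma adjusted p = 0.0176, n = 8 sows), AMY2, an amylase (0.88 ± 0.12, 1.84-fold), and MGST1, a microsomal glutathione transferase (0.86 ± 0.12, 1.82-fold). The largest falls were in IHH, the hedgehog ligand through which granulosa cells signal to theca cells (-1.93 ± 0.35, 3.8-fold lower, adjusted p = 0.0232), MYBL2, a transcription factor of dividing cells (-1.16 ± 0.20, 2.24-fold lower), FABP3, a fatty acid carrier (-1.08 ± 0.17, 2.12-fold lower), and LDHA, which makes lactate (-1.06 ± 0.25, 2.09-fold lower, adjusted p = 0.04). Each of these 7 genes had the same sign in all 8 sows, as the rule for naming required, and the ranking is among such genes. The fall of IHH rests on the brightest of 3 probes, as the other probes gave -0.28 and -0.19.

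Other genes that rose in all 8 sows were SELENOP, a selenium carrier (0.79 ± 0.12), NABP1, which binds single-stranded DNA (0.79), the transcription factor KLF2 (0.68), ITM2B (0.63), the glutathione transferase GSTA2 (0.61), PLEKHO1 (0.56) and PIK3IP1, an inhibitor of PI3 kinase (0.56). PDK4, which restrains entry of pyruvate into mitochondrial oxidation, rose in all 8 too (0.55). STRA6, a receptor for retinol-binding protein, fell in all 8 sows (-0.84, with its other probes at -0.09 and -0.04). So did the replication factor CDC45 (-0.80), the cytokine MIF (-0.74) and the mitotic kinase CDK1 (-0.74). INHBB, the B subunit of activin and inhibin (-0.67 ± 0.13), LMNB2, a nuclear lamin (-0.66), ASRGL1 (-0.66) and JPT1 (-0.62) fell in all 8 as well.

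In all, 979 of 15727 features passed the threshold, 351 higher and 628 lower in large follicles. Of these, 492 had a gene symbol, 9 changed by 2-fold or more and 84 by at least 1.5-fold. All 979 had the same direction in HighVAR and LowVAR sows, and 563 had the same sign in all 8 sows. The 979 were chosen by the mean effect of both groups, which favours such agreement. Among all 15727 features, 59.7% had the same direction in both groups. Of the fixed panel of 17 measured marker genes, 3 passed. AMH, a product of growing follicles, fell by 0.51 ± 0.07 on the log2 scale (adjusted p = 0.0186), while its 2 dimmer probes stayed near 0 (-0.072 and -0.001). LHCGR, the receptor for luteinizing hormone, rose (0.61 ± 0.13, adjusted p = 0.0289), and so did IGF1 (0.32 ± 0.08, adjusted p = 0.0418). The receptor for follicle-stimulating hormone, FSHR, did not pass (-0.24 ± 0.06, adjusted p = 0.0567). Neither did CCND2, a cyclin of granulosa cells (-0.47 ± 0.14, 0.0871), VEGFA (-0.36 ± 0.12, 0.0979), INSL3, a theca product (-0.20 ± 0.07, 0.115), or the enzymes of steroid synthesis HSD3B1 (0.13 ± 0.05, 0.133), CYP11A1 (0.17 ± 0.11, 0.412), STAR (0.09 ± 0.08, 0.564) and CYP19A1, aromatase (-0.005 ± 0.059, 0.973).

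**Figure D2:**
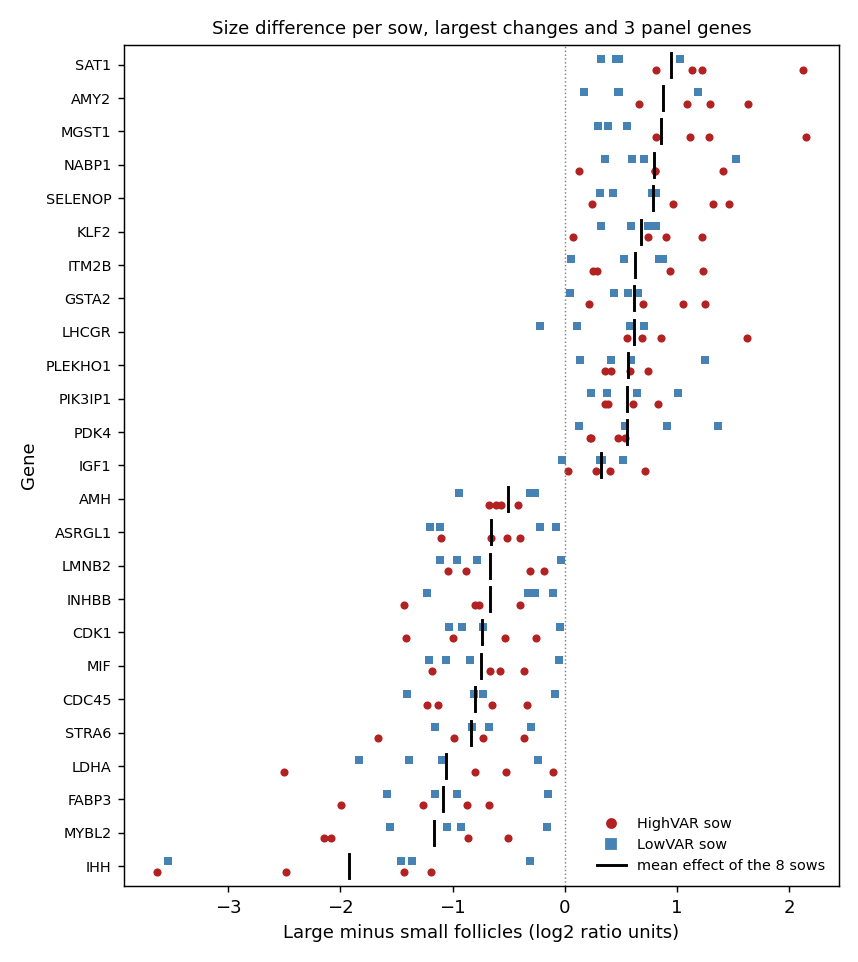
Difference between large and small follicles (log2 ratio units, x axis) for 22 genes and the 3 panel genes past the threshold (y axis), with 1 point per sow (circles HighVAR, squares LowVAR) and a bar at the mean effect. The 22 are the 11 largest changes in each direction among genes past the threshold with one sign in all 8 sows. SAT1 lies at 0.95 and IHH at -1.93 on average.

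The gene lists tested with camera, at a preset correlation between genes, gave 14 of 32 past the threshold, 9 lower and 5 higher in large follicles. With an estimated correlation none of the 14 passed, and the lowest adjusted p was 0.289, while fry called 10 and the exact test of list means 12 of 32. The mitotic cell cycle list fell (median -0.40), with 10 of 14 measured members lower and 14 when adjusted over the list alone (camera adjusted p = 4.34e-11, adjusted p = 0.289 with an estimated correlation). Over the alternatives its median ranged from -0.91 to -0.32. Among its members, CDC20, an activator of the anaphase complex, fell by 0.38 and AURKA, a spindle kinase, by 0.31. DNA replication fell (median -0.48), with 6 of 8 members lower and 8 when adjusted over the list alone (camera adjusted p = 1.11e-07, adjusted p = 0.289 with an estimated correlation), among them PRIM1, the primase subunit (-0.59), and MCM5 of the replicative helicase (-0.45). The median of this list ranged from -0.99 to -0.35 over the alternatives.

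Members of lists of energy metabolism and protein folding fell as well. Of 12 glycolytic genes 7 fell, and 9 when adjusted over the list alone (median -0.49, camera adjusted p = 2.29e-06, adjusted p = 0.289 with an estimated correlation), including TPI1 (-0.54), ALDOC (-0.54) and GAPDH (-0.50). Of 24 oxidative phosphorylation genes 9 fell, and 15 when adjusted over the list alone (median -0.26, camera adjusted p = 1.05e-10, adjusted p = 0.289 with an estimated correlation), including NDUFV2 of complex I (-0.39) and ATP5O of the ATP synthase (-0.30). The heat shock list fell in 4 of 10 members, and in 4 when adjusted over the list alone (median -0.22, camera adjusted p = 0.00167, adjusted p = 0.402 with an estimated correlation), with HSPH1 at -0.43 and HSPA8 at -0.37. The unfolded protein response list fell in 4 of 11 members, with 6 lower and 1 higher when adjusted over the list alone (median -0.12, camera adjusted p = 0.00411, adjusted p = 0.408 with an estimated correlation), and its changed members were the chaperones HSPA5 (-0.53), HSP90B1 (-0.52), CALR (-0.48) and PDIA4 (-0.37). Cholesterol synthesis and uptake fell in 3 of 15 members, and in 5 when adjusted over the list alone (median -0.14, camera adjusted p = 0.000421, adjusted p = 0.408 with an estimated correlation), led by MVK, mevalonate kinase (-0.41).

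Smaller shifts downward were found in 2 lists. Cytosolic ribosomal proteins had a median of -0.09, with 2 members higher (RPL32, 0.34, and RPL13A, 0.28) and 2 lower (RPL12, -0.31, and RPL14, -0.22) of 50, and the same numbers when adjusted over the list alone (camera adjusted p = 0.00564, adjusted p = 0.654 with an estimated correlation). For RPL32 and RPL14, other probes gave the opposite sign, and the list call was lost without sow H2279 (adjusted p = 0.229) and without sow L2633 (0.0937). Lipid uptake, storage and fatty acid metabolism had a median of -0.02 and a mean of -0.13, with 3 of 23 members lower (FABP3, the lipase LIPE, -0.28, and ACSL3, -0.27) and 1 higher (ACSL4, 0.36, with 1 of its other 5 probes of opposite sign). Adjusted over the list alone these numbers were 7 and 1 (camera adjusted p = 0.0442, adjusted p = 0.521 with an estimated correlation). That call was lost without sow L1808 (adjusted p = 0.114), H2124 (0.129), L2633 (0.0977) or L2673 (0.0765) and with array brightness as a covariate (0.109), and the list median turned positive, at 0.02, with the deposited value table.

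Among lists that rose, the IGF system had 4 of 14 members higher, and 6 when adjusted over the list alone (median 0.20, camera adjusted p = 0.00136, adjusted p = 0.289 with an estimated correlation). They were IGF1 and the binding proteins IGFBP2 (0.66), IGFBP4 (0.40) and IGFBP7 (0.33), which hold IGF away from its receptor. Immediate early genes, which answer to acute stimuli, had 2 of 11 members higher, JUN (0.45) and FOSL2 (0.40), and 4 when adjusted over the list alone (median 0.23, camera adjusted p = 0.00842, adjusted p = 0.289 with an estimated correlation). The interferon response had 0 of 14 members past the threshold, and 0 when adjusted over the list alone, with a median of 0.09 (camera adjusted p = 0.0442, adjusted p = 0.474 with an estimated correlation). That call was lost without sow H2124 (adjusted p = 0.0985), L2434 (0.39), L2633 (0.0937) or H2684 (0.0692), and with array brightness as a covariate (0.176). In all it was lost under 12 of 21 alternatives, among them no background correction, the processed signals, Cy5 alone, the filter at 80% and both fits of 44 arrays.

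Lists kept as markers of other cell types moved with size too. The endothelial list was higher in large follicles (median 0.11 over 5 members, camera adjusted p = 0.0339, adjusted p = 0.408 with an estimated correlation), with VWF (0.23) past the threshold, 2 members when adjusted over the list alone, and PECAM1 at 0.11 not past it (adjusted p = 0.421). That call was lost without sow L1808 (adjusted p = 0.0595), L2633 (0.0937), H2684 (0.0528) or H2723 (0.0609). In all it was lost under 9 of 19 alternatives, among them the processed signals, Cy5 alone and both fits of 44 arrays. The luteal list was higher (median 0.17 over 7 members, camera adjusted p = 0.0442, adjusted p = 0.408 with an estimated correlation), with LHCGR and PTGFR, a prostaglandin receptor (0.49), past the threshold and 4 higher and 1 lower when adjusted over the list alone. It was lost without sow H2124 (adjusted p = 0.0638), L2434 (0.144), L2633 (0.102) or H2684 (0.0571). In all it was lost under 10 of 21 alternatives, among them Cy5 alone, the filter at 80%, the deposited value table and both fits of 44 arrays. The luteal list shares 3 measured members with steroidogenesis, so its rise does not by itself point to another cell type. Theca markers (1 of 12 past, LHCGR, camera adjusted p = 0.731), macrophage markers (1 of 10, CD163, 0.22, camera adjusted p = 0.112), smooth muscle markers (0 of 6, camera adjusted p = 0.455) and oocyte markers (0 of 6, camera adjusted p = 0.944) did not pass as lists. Nor did steroidogenesis, with 0 of 14 members past the threshold and 2 lower when adjusted over the list alone (median -0.04, camera adjusted p = 0.327), or apoptosis and follicle atresia, with 0 of 18 and 0 (median -0.07, camera adjusted p = 0.162).

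**Figure D3:**
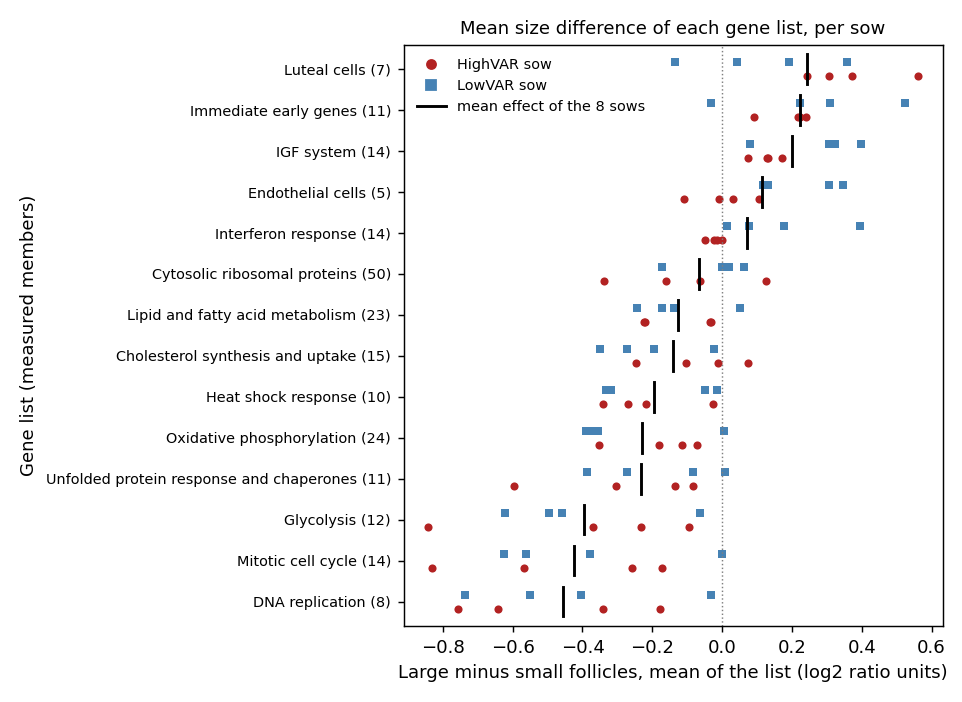
Mean difference between large and small follicles over the measured members of each list (log2 ratio units, x axis) for the 14 lists past the camera threshold (y axis, measured members in parentheses), with 1 point per sow (circles HighVAR, squares LowVAR) and a bar at the mean effect of the 8 sows. All 8 sows lie below 0 for DNA replication, glycolysis and heat shock, and all 8 lie above 0 for the IGF system.

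The number of features past the threshold depended on single sows. Against 979 with all 8, it was 0 without sow H2124, 0 without L2673, 77 without L2633, 239 without L1808, 250 without H2279, 499 without H2684 and 1759 without L2434. It was 1784 with the 44 arrays as separate values, 1419 with slide as a random block among them and 315 with no block for the pairing by sow (14% of them higher). It was 346 without the 3 arrays below 30% detection and 0 with the brightness difference of each sow as a covariate. The direction of the 66 named genes past the threshold was the same under every alternative in which they were measured. That was 63 of them with the deposited value table, 65 with the filter at 80% of arrays and 66 otherwise. The choice of genes largely fixed this, since all were past the threshold in these data. The largest changes also had to share a sign in all 8 sows, so leaving out a sow could not reverse them. The shared direction is therefore no separate support.

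Within HighVAR sows, whose follicles differ most in size, the 3 genes with the largest rises over all sows were again among those with the smallest p. MGST1 was 2.54-fold higher in large follicles (1.34 ± 0.17, n = 4 sows), SAT1 2.5-fold (1.32 ± 0.18) and AMY2 2.25-fold (1.17 ± 0.17), each with an adjusted p of 0.0556, just short of the threshold. ZFAND5 stood at 0.42 (adjusted p = 0.0568), while PRKCE, protein kinase C epsilon (-0.46, adjusted p = 0.0553), EML4 (-0.46), PTGES3, a cochaperone (-0.58), and the proteasome subunit PSMA4 (-0.49) stood lower. LHCGR was 1.91-fold higher (0.93 ± 0.18, adjusted p = 0.0727) and AMH 1.48-fold lower (-0.57 ± 0.10, adjusted p = 0.0659), and none of the 17 panel genes passed.

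With limma, 0 features passed in HighVAR sows, with 2458 at an unadjusted p under 0.05. Camera called 8 of 32 lists, 7 lower and 1 higher, where the estimated correlation and fry called 0. The exact test called 0 too, but with 4 sows its p cannot be under 0.125, so it could call none. Mitotic cell cycle (median -0.42), DNA replication (-0.52), glycolysis (-0.46), oxidative phosphorylation (-0.19), heat shock (-0.21), unfolded protein response (-0.28) and ribosomal proteins (-0.14) were lower, with camera adjusted p from 7.56e-09 to 0.00616 and adjusted p = 0.537 at the lowest with an estimated correlation. Members past the threshold numbered 0 in each of these lists. Adjusted over the list alone they numbered 11 of 14 mitotic, 7 of 8 replication, 7 of 12 glycolytic, 5 of 11 unfolded protein response, 4 of 10 heat shock, 1 of 24 oxidative phosphorylation and 0 of 50 ribosomal genes. The luteal marker list was higher (median 0.36, camera adjusted p = 0.0172, adjusted p = 0.537 with an estimated correlation), with RGS2 at 0.87 and CYP11A1 at 0.42. This list shares 3 measured members with steroidogenesis, so its rise does not by itself point to another cell type. Of its 7 members 0 passed, against 3 higher and 1 lower when adjusted over the list alone.

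The count of 0 in HighVAR sows changed with several choices. It became 444 of 7949 features with the deposited value table and 24 of 10622 with the filter at 80% of arrays. It was 690 with 44 arrays as separate values and 597 with slide as a random block. It was 14 without the dimmest array, 12 with the mean of all probes, 12 with Cy5 alone, 6 without the 3 dimmest arrays and 2 without a filter. Without single sows it was 106 (H2723), 135 (L2434, a LowVAR sow that only adds to the spread), 5 (L1808), 1 (H2279, MGST1) and 1 (L2633, AMH). List calls were lost for ribosomal proteins without H2279 (adjusted p = 0.475) or H2723 (0.0544), for the unfolded protein response without H2279 (0.0784) and for luteal markers without H2124 (0.05). The luteal call was lost under 6 of 21 alternatives in all, among them the processed signals, the deposited value table and both fits of 44 arrays.

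Within LowVAR sows the smallest p belonged to other genes. PPP4R3A (0.56 ± 0.09, 2 of its other 4 probes of opposite sign), IGFBP7 (0.52 ± 0.09), FAM13C (0.43) and SSPN (0.38) stood higher in large follicles, and VDAC2, a mitochondrial pore protein (-0.47 ± 0.07), CBX2 (-0.38, its other probe of opposite sign), TUFM, a mitochondrial elongation factor (-0.37), and FAN1 (-0.34) stood lower, all at an adjusted p of 0.095 (n = 4 sows). IGFBP4, which binds IGF, was 1.69-fold higher (0.76 ± 0.14, adjusted p = 0.095). LDHA stood at -1.14 ± 0.35 (adjusted p = 0.141) and AMH at -0.45 ± 0.10 (adjusted p = 0.095), and LHCGR at 0.30 ± 0.18 (adjusted p = 0.413).

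With limma, 0 features passed in LowVAR sows, with 2971 at an unadjusted p under 0.05. Camera called 17 of 32 lists, 11 lower and 6 higher, where the estimated correlation called 0 and fry 1. The exact test called 0, but with 4 sows it could call none. Oxidative phosphorylation had the smallest p (median -0.26, 15 of 24 members lower when adjusted over the list alone, camera adjusted p = 4.2e-11, adjusted p = 0.292 with an estimated correlation), with NDUFB8 at -0.42 and ATP5A1 at -0.46. Mitotic cell cycle (-0.39), DNA replication (-0.43), glycolysis (-0.41), cholesterol synthesis (-0.20), heat shock (-0.21), unfolded protein response (-0.08), steroidogenesis (-0.12), oxidative stress and glutathione (-0.13), apoptosis (-0.08) and lipid metabolism (-0.06) were lower too. The IGF system, the list that fry called (fry adjusted p = 0.0437), was higher (median 0.26, camera adjusted p = 0.0014, adjusted p = 0.292 with an estimated correlation). Immediate early genes (0.31), the extracellular matrix (0.17) and the interferon response (0.15) were higher, as were the cell-type markers of endothelium (0.21) and macrophages (0.07). These 17 lists had camera adjusted p values from 4.2e-11 to 0.0453 and adjusted p = 0.292 to 0.41 with an estimated correlation. Their members past the threshold numbered 0. Adjusted over the list alone, 8 mitotic, 7 replication, 7 glycolytic, 3 cholesterol and 3 heat shock genes were lower and 4 endothelial, 4 matrix, 3 interferon and 2 IGF genes higher.

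Without sow L2434 the count in LowVAR sows was 1216 features, and it was 415 with 44 arrays as separate values and 272 with slide as a random block. Camera called 11 lists without sow L1808, and 11 with no block for the pairing by sow. Single calls were lost for heat shock without L1808 (adjusted p = 0.0668), for steroidogenesis without L1808 (0.105) or L2673 (0.0808), for the unfolded protein response without L1808 (0.243) or L2673 (0.0824), and for oxidative stress without L1808 (0.0673) or L2633 (0.0688). They were lost too for immediate early genes without L1808 (0.0504) or L2633 (0.0571), and for interferon without L2434 (0.142). The same held for apoptosis without L1808 (0.105), L2434 (0.0539) or L2673 (0.0803), for lipids without L1808 (0.105), L2633 (0.0508) or L2673 (0.0824), and for macrophage markers without H2279 (0.0534), L2434 (0.773) or H2684 (0.0504).

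Whether the size effect differed between the sow groups was tested directly. The smallest p belonged to FRS2, an adaptor of growth factor receptors. Its large minus small change was 0.55 ± 0.08 higher in HighVAR than in LowVAR sows (limma adjusted p = 0.181, n = 4 against 4 sows). NPY1R (0.66) and ZFAND5 (0.52) followed and, with a lower change in HighVAR sows, PRKCE (-0.37) and DPH3 (-0.44). MGST1 differed by 0.96 ± 0.24 (adjusted p = 0.463) and LHCGR by 0.63 ± 0.26 (adjusted p = 0.522). Limma called 0 features here, with 1435 at an unadjusted p under 0.05 and 0 under every alternative.

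For 7 lists camera found a difference in size effect, where the estimated correlation, fry and the exact test found 0. The large minus small change of the oxidative stress and glutathione list was higher in HighVAR than in LowVAR sows (median difference 0.17, camera adjusted p = 0.0026, adjusted p = 0.6 with an estimated correlation). Its mean change was 0.072 in HighVAR and -0.09 in LowVAR sows, and its median was -0.13 in LowVAR sows. Steroidogenesis (0.22), cholesterol synthesis (0.12) and oxidative phosphorylation (0.11) shifted the same way. For cholesterol synthesis that was a weaker fall in HighVAR (mean -0.072) than in LowVAR sows (-0.21). For oxidative phosphorylation it was so too (-0.18 against -0.278). The extracellular matrix (-0.16), the interferon response (-0.14) and endothelial markers (-0.23), with PECAM1 at -0.50 and KDR at -0.29, shifted the other way. For these 6 lists the adjusted p was 0.6 to 0.729 with an estimated correlation. Members past the threshold numbered 0 in all 7, and adjusted over the list alone 2 endothelial genes and 1 interferon gene were lower. The number of lists was 11 without a filter, 3 with 44 arrays, 3 with slide as a random block and 3 with no block for the pairing, and 2 without sow H2723, 4 without L1808 and 4 without L2673. Only the oxidative stress list kept its call without each sow. Calls were lost for steroidogenesis without H2723 (adjusted p = 0.0777), L1808 (0.13) or L2673 (0.0999), for cholesterol without H2723 (0.0777) or L2673 (0.0574), and for interferon without H2723 (0.0777) or L2434 (0.182). Endothelial markers lost theirs without H2279 (0.074) or L1808 (0.0698), oxidative phosphorylation without H2684 (0.0915), H2723 (0.0777), L1808 (0.156), L2633 (0.0638) or L2673 (0.107), and the extracellular matrix without H2279 (0.173), H2723 (0.0777), L2434 (0.0908), L2633 (0.214) or L2673 (0.0525).

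Across features, the size effects of HighVAR and LowVAR sows correlated with Pearson's r = 0.494 (p = 0.0469) and Spearman's rho = 0.334 (p = 0.0625), from 128 sign patterns of the 8 sow differences in an exact permutation test, with an adjusted p of 0.0625 for each of the 2 coefficients. Features are not independent replicates. Of 933 features with an unadjusted p under 0.05 in both sow groups, 867 had the same direction in both, and of all features 59.7% did. The adjusted p of r was 0.0312 with the processed signals of the scanner (r = 0.452), 0.0469 with Cy5 alone (r = 0.493) and 0.0312 without sow H2684 (r = 0.556).

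HighVAR and LowVAR sows were then compared on the mean of their follicles, which asks whether granulosa cells differ between sows with uneven and even follicles. The smallest p belonged to HADHA, an enzyme of mitochondrial fatty acid oxidation, which was 1.36-fold higher in HighVAR sows (0.44 ± 0.05, adjusted p = 0.444, n = 4 against 4 sows), though its other 2 probes had the opposite sign. GRK5, a receptor kinase (0.77 ± 0.14), TBC1D4, a regulator of glucose transporter traffic (0.75 ± 0.14), and AGPAT4 (0.36) stood higher. The protease ADAMTS1 (-0.64 ± 0.14), CYR61, a matrix-associated immediate early gene (-0.58 ± 0.13), S100A6 (-0.37) and RGS5 (-0.32) stood lower, all with an adjusted p of 1. Of the panel, INHBA, the A subunit of activin and inhibin, stood at 0.82 ± 0.29, INSL3 at -0.69 ± 0.32 and CCND2 at 0.39 ± 0.16, and none of the 17 genes passed.

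Immediate early genes were the list with the smallest p, lower in HighVAR sows, with all 11 measured members on that side (median -0.11, mean -0.22, camera adjusted p = 6.45e-05, adjusted p = 0.0865 with an estimated correlation). No member passed the threshold and 4 did when adjusted over the list alone, among them FOSL2 (-0.39) and CTGF (-0.50). The exact test of the list mean gave p = 0.0571 (adjusted p = 0.626 over 32 lists). Markers of smooth muscle and pericytes were lower in the same sows (median -0.33 over 6 members, camera adjusted p = 0.00906, adjusted p = 0.597 with an estimated correlation), with CNN1 at -0.44 and ACTA2 at -0.35, as were theca (median -0.12) and endothelial markers (-0.15), each with a camera adjusted p of 0.0329 and an adjusted p of 0.597 with an estimated correlation. Matrix proteases (-0.19), apoptosis (-0.05) and interferon genes (-0.05) were lower, and oxidative phosphorylation (0.11), cholesterol synthesis (0.06), oxidative stress (0.06) and lipid metabolism (0.04) higher, with camera adjusted p from 0.00906 to 0.0456 and an adjusted p of 0.597 with an estimated correlation. Members of the 11 lists past the threshold numbered 0, and adjusted over the list alone 1 protease gene and 1 smooth muscle gene were lower and 1 lipid gene higher.

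Limma called 0 features between HighVAR and LowVAR sows, with 594 at an unadjusted p under 0.05, 0 in large follicles alone (809) and 0 in small follicles alone (565). Camera called 11 of 32 lists, and the estimated correlation, fry and the exact test called 0. With slide as a fixed term and sow as a random block 9 features passed, none of which passed on sow means. Named among the 9 after their values were seen, PGM1, a glycogen enzyme (0.91), TBC1D4 (0.78), GRK5 (0.79) and HADHA (0.44) were higher and CD9 (-1.34) lower in HighVAR sows. That fit took each array as a value, with a shared within-sow correlation of 0.15, although the contrast lies between sows. The same kind of fit gave 1813 features for a split of the sows that follows neither grouping, picked for its high count. The 9 calls therefore do not establish a difference between HighVAR and LowVAR sows. The immediate early list shifted by -0.24 with slide as a block (adjusted p = 9.67e-05) and downward in 9 of 11 slides (-0.73 to 0.11 within slides), and the smooth muscle list by -0.26 (adjusted p = 0.00227) and downward in 10 of 11 slides (-0.57 to 0.15). Over the other 9 lists the shift with slide as a block had the sign of the pooled one, and within slides it did so in 6 to 9 of 11. The interferon (adjusted p = 0.0699) and apoptosis (0.152) lists no longer passed with slide as a block. Within single slides limma called 0 features in 10 of 11 and 19 in the other, with 392 to 1964 at an unadjusted p under 0.05. The number of lists was 7 with Cy5 alone, 6 with the filter at 80%, 7 with the deposited value table and 2 with COC group as a covariate. In large follicles alone 1 feature passed without L2434, 1 without L2633 (TBC1D4) and 1 with the filter at 80% (TBC1D4, 0.95).

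Only the immediate early list kept its call without each sow. Camera called 1 list without sow L2633, where 10 calls were lost at an adjusted p of 0.0966 to 0.249 (smooth muscle markers 0.11), and 3 without H2279, where 9 were lost at 0.123 to 0.913. It called 5 without L2434 (6 lost, 0.0504 to 0.742) and 7 without H2723 (4 lost, 0.0973 to 0.334). Without L2673 the apoptosis (0.468), lipid (0.468), cholesterol (0.246) and oxidative stress (0.106) calls were lost. Without L1808 the theca (0.2), endothelial (0.091), protease (0.0872) and oxidative stress (0.0706) calls were lost, without H2124 the theca (0.0658), endothelial (0.0617) and interferon (0.0573) calls, and without H2684 the interferon (0.134) and apoptosis (0.0928) calls.

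**Figure D4:**
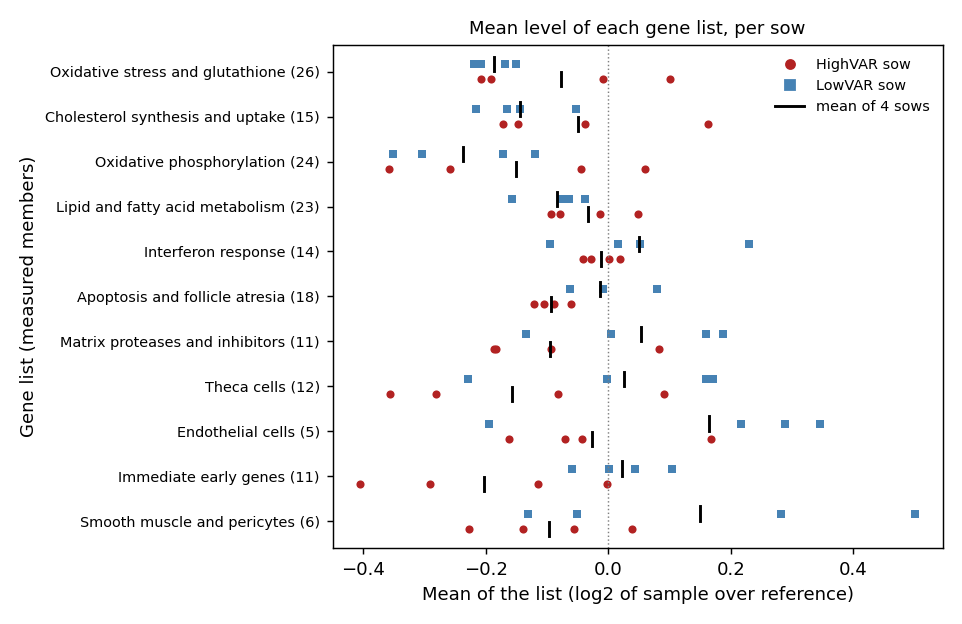
Mean log2 ratio of sample over reference across the measured members of each list (x axis) for the 11 lists past the camera threshold between HighVAR and LowVAR sows (y axis, measured members in parentheses), with 1 point per sow (circles HighVAR, squares LowVAR) and bars at the mean of the 4 sows of each group. The sows of both groups overlap in every list, including immediate early genes, where the mean shift is -0.22.

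HighCOC and LowCOC sows were compared in the same way, which asks whether granulosa cells differ with the health of the oocytes. CHCHD10, a mitochondrial protein (0.24 ± 0.04), ANGPTL4, an inhibitor of lipoprotein lipase (0.38 ± 0.08), ACSL3, which activates fatty acids (0.17), and MFSD12 (0.17) stood higher in HighCOC sows. PPARG, a regulator of lipid genes (-0.34 ± 0.07), NREP (-0.59 ± 0.13), RUNX1T1 (-0.26) and NAB2 (-0.17) stood lower, all with an adjusted p of 0.936 (n = 4 against 4 sows). Camera called 5 of 32 lists. Oxidative stress and glutathione (median 0.07, camera adjusted p = 0.00353), lipid metabolism (0.05, 0.0126), cholesterol synthesis (0.09, 0.0131) and steroidogenesis (0.06, 0.0195) were higher and immediate early genes (-0.15, 0.0195) lower in HighCOC sows, each with an adjusted p of 0.808 with an estimated correlation. Examples were GPX3, an extracellular peroxidase (0.33), SCD (0.47), FDXR (0.53) and FOSL2 (-0.43), and no member of the 5 lists passed. Adjusted over the list alone 1 lipid gene was higher, 1 lower, and 1 immediate early gene lower.

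Limma called 0 features between HighCOC and LowCOC sows, with 729 at an unadjusted p under 0.05, and the estimated correlation, fry and the exact test called 0 lists. With slide as a fixed term and sow as a random block 6 features passed, of which PLOD2, a collagen-modifying enzyme (-0.64, named after its value was seen), had a symbol. None of the 6 passed on sow means. That fit took each array as a value, with a shared within-sow correlation of 0.144, although the contrast lies between sows. The 6 calls therefore do not establish a difference between HighCOC and LowCOC sows. The list shifts with slide as a block were 0.09 for oxidative stress, 0.06 for lipids, 0.09 for cholesterol, 0.07 for steroidogenesis (adjusted p = 0.0838, no longer past the threshold) and -0.19 for immediate early genes. Within slides they had the pooled sign in 7 to 9 of 11, and limma called 0 features in each (201 to 1092 at an unadjusted p under 0.05). These fits say little on COC alone, since in 6 slides 1 group had a single array, taken to vary like the other group, and in 3 others the split was the same as that by VAR. Array brightness moved with this grouping, as the detected share was lower in HighCOC sows by -6.67 points (exact p = 0.0857, adjusted p = 0.205 over 7 tests). With brightness as a covariate 12 lists were called, of which 3 were among these 5, as the immediate early (adjusted p = 0.0761) and lipid (0.0686) calls were lost. Lists called numbered 1 with VAR group as a covariate, 1 without a filter, 1 without sow H2279, 1 without H2684, 3 without L1808 and 11 without L2633. Calls were lost for oxidative stress without H2279 (adjusted p = 0.381) or H2684 (0.0551), for lipids without H2279 (0.208), H2684 (0.0551) or L2673 (0.0736), and for cholesterol without H2279 (0.625), H2684 (0.126) or L2673 (0.0597). Steroidogenesis lost its call without H2279 (0.504), H2684 (0.176), H2723 (0.0726), L1808 (0.0537) or L2673 (0.0607), and immediate early genes lost theirs without H2124 (0.135) or L1808 (0.148).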

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

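The other groupings of the sows and the Cy3 test of the slides were set before the result was seen, and the brightness test was chosen after it had been seen.

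Outliers were sought among the 4 sows of each group in 198 sets of values, and a sow counted as one when Dixon's ratio of its gap to the range passed the 5% critical value, so that chance picks about 1 in 20 groups. It found 8, where 9.9 are expected by chance. In HighVAR sows they were AURKA (ratio 0.836; sow H2723 at -0.02, the others -0.43 to -0.36), NDUFB8 (0.842; H2124 at -0.43, the others -0.21 to -0.17) and the mean of the immediate early genes (0.842; H2684 at 0.09, the others 0.22 to 0.24), all as large minus small follicles. In LowVAR sows they were AMH (0.935; L2633 at -0.94, the others -0.31 to -0.26), TPI1 (0.963; L2434 at 0.05, the others -0.75 to -0.72), RPL32 (0.898; L1808 at 0.68, the others 0.22 to 0.27), the mean of the oxidative phosphorylation genes (0.915; L2434 at 0.006, the others -0.39 to -0.36) and the log2 Cy5 signal itself (0.928; L2633 at 0.76, the others -0.70 to -0.60).

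A difference of the size effect between HighVAR and LowVAR sows was called by camera for 7 lists, by adjusted p: oxidative stress and glutathione (0.0026), cholesterol synthesis (0.00991), oxidative phosphorylation (0.0149), interferon response (0.0149), endothelial cells (0.0149), steroidogenesis (0.0222) and extracellular matrix (0.0317). No gene passed in that comparison. With a real count of 0, all 35 of the 35 splits of the 8 sows into 4 and 4 gave as many by construction (the highest other gave 16), so the splits neither exclude chance nor speak for it, and they do not test the lists. Adjusted p = 0.6 was the lowest for these lists with an estimated correlation.

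Each slide held follicles of 1 size, so a slide effect that reaches Cy3 would change the reference between large and small arrays. There 0 of 15727 features passed the threshold (1109 in Cy5 alone). Yet 3131 had p < 0.05 in limma (4128 in Cy5), more than chance alone gives, and the lowest adjusted p was 0.0799. The mean square of Cy3 between slides was 1.53 (large) and 1.64 (small) times that within them, as medians over features. This ratio is about 1 without a slide effect. The Cy3 change had an r of 0.0973 with that of the log ratio, and the 979 called features shifted by a median of 0.30 in the log ratio, 0.52 in Cy5 and 0.03 in Cy3. The reference channel thus added little to these calls. A slide effect equal in both dyes cancels in the ratio, so these values do not test it, and one of Cy5 labelling or RNA input stays open. Both channels were processed signals normalized between the dyes, so Cy3 is not independent of Cy5. Of 100 sign patterns drawn from the 128 of the 8 sows, 1 of the 100 gave as many features, the real one (979, where the highest other gave 616, with only sow L2434 turned, and 97 gave 0). The sows thus share a direction more than random signs would give. Sows shared slides of 1 size, so a Cy5 effect of slide or labelling would give the same pattern, and the flips cannot exclude it. With the brightness of the arrays as a covariate, the median change of the 979 features kept 91.5% of its size, from 0.30 (quartiles 0.22 to 0.41, median SE 0.061) to 0.28 (0.21 to 0.37, SE 0.077), all in the same direction and 973 at p < 0.05. None passed any more, as the wider SE and 5 instead of 6 residual degrees of freedom ended the calls, so brightness does not explain most of the median change but no single gene could be called with it in the model.

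The comparisons within 4 sows allow only 8 sign patterns each, too few to tell: 8 of the 8 patterns gave as many genes as the real one in HighVAR sows (0; highest other 0) and 8 of 8 in LowVAR sows (0; highest other 1). Between sows the real counts were 0 too, so that 35 of the 35 splits gave as many as HighVAR against LowVAR (highest other 815) and 35 of 35 as many as HighCOC against LowCOC (highest other 815) by construction, and the splits say nothing on chance for either. The split with 815 follows neither grouping and was picked as the highest of the 35. Whether it reflects a structure of the samples, biological or technical, or the extreme of many splits was not tested.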

How the results depend on the processing

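Chosen after seeing the data were the runs without dim arrays, the brightness covariate, the exact list test and the within-slide fits. For the cause of each change below, the cause was not tested, except that fewer sows or arrays leave fewer values and fits of the 44 arrays, with or without slide as a block, add residual degrees of freedom.

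For large against small follicles, 979 features became 1784 with the 44 arrays as separate values, 315 with no block for the pairing by sow, 346 without the 3 arrays under 30% detection, 0 with the brightness covariate and 0 to 1759 without single sows. Without local background subtraction (1145), with the processed signals of the scanner (675) and with Cy5 alone (1109) the count stayed within 1.5 times. It did so too with other filters (724 and 1027), the mean of all probes (953) and the deposited value table (1207). The features called differed, as 419 of the 979 were called with the processed signals, 543 with Cy5 alone and 672 with the deposited value table. Features tested numbered 15727 in the main run, 7949 with that table, 10622 with the filter at 80% and 35720 with no filter. In HighVAR sows 0 became 12 with Cy5 alone, 2 (PRKCE and EML4) with no filter, 24 with the filter at 80% of arrays, 12 with the mean of all probes, 444 with the deposited value table, 690 with 44 arrays, 597 with slide as a random block, 14 without the dimmest array, 6 without the 3 dimmest and 0 to 135 without single sows. In LowVAR sows it became 415 with 44 arrays, 272 with slide as a random block and 0 to 1216 without single sows.

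Between HighVAR and LowVAR sows 0 became 9 with slide as a block and 19 within slide 5, and 1 in large follicles with the filter at 80% (0 to 1 without single sows). Between HighCOC and LowCOC sows 0 became 6 with slide as a block. The correlation of size effects (0.494) was past the threshold with processed signals (0.452) and Cy5 alone (0.493), and was 0.424 to 0.556 without single sows.

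The number of lists past the threshold, with an estimated correlation, was 0 in all 6 comparisons. With fry it was 0 in HighVAR sows, 1 in LowVAR sows, 0 for the difference of size effects, 0 for VAR and 0 for COC, and with the exact test, which could call none within 4 sows, 0 in each of these 5. With no block for pairing it was 11 in LowVAR sows and 3 for the difference of size effects, and 11 of the 14 for size, where the interferon (adjusted p = 0.0599), endothelial (0.261) and luteal (0.196) calls were lost. In HighVAR sows 6 of 8 calls were kept, without heat shock (0.0913) and luteal markers (0.162), and the missing block changed no gene count other than that for size. The difference of size effects gave 11 lists with no filter, 3 with 44 arrays and 3 with slide as a random block. VAR gave 7 with Cy5 alone, 6 with the filter at 80%, 7 with the deposited value table and 2 with COC as a covariate. COC gave 1 with no filter, 1 with VAR as a covariate and 12 with the brightness covariate. That covariate also ended calls for interferon (adjusted p = 0.176) and lipids (0.109) for size, unfolded protein response in HighVAR sows (0.0794), apoptosis (0.106), unfolded protein response (0.105), macrophages (0.0539) and lipids (0.0527) in LowVAR sows, extracellular matrix for the difference (0.127), and apoptosis (0.0839), cholesterol (0.053), interferon (0.0518) and oxidative stress (0.0518) for VAR. Without single sows the lists numbered 9 to 15 (size), 7 to 10 (HighVAR), 11 to 17 (LowVAR), 2 to 9 (difference), 1 to 14 (VAR) and 1 to 11 (COC).

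No called value reversed in its test, but the medians of 4 called lists changed sign under 1 alternative each, those of lipid metabolism for size (to 0.023), of interferon (0.003) and oxidative stress (-0.001) for VAR and of oxidative stress for COC (-0.007). For the genes, chosen as past the threshold in these data, the lack of reversals was largely fixed by that choice. Of the named values under the alternatives 8057 were the same, 812 weaker, 262 stronger and 117 moved. The same here includes values past the threshold in neither run, which most named values were. Of the 66 named size genes past the threshold, all 66 lost their call without H2124, without L2673 and with the brightness covariate. The lists of mitosis, DNA replication, glycolysis, oxidative phosphorylation, heat shock, unfolded protein response, cholesterol synthesis, IGF system and immediate early genes kept their size call under every setting in which they were tested, with camera at its preset correlation. These were 20 alternatives for DNA replication and 21 for each of the others. A planned run with quantile normalization of the average intensities gave no separate value, since it changed no log ratio (largest change 0). Cy5 detected 26.16% to 54.53% of probes per array, and the 22726 probes below the filter were not tested.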

Other observations

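The hypothesis on the size response was tested after the size result had been seen, and genes outside the rule are named after their values were seen.

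Some further genes passed the threshold within lists that did not pass as a whole for large against small follicles. GJA1, the gap junction protein that couples granulosa cells, rose by 0.52 ± 0.11, SERPINE2, a protease inhibitor, by 0.47 ± 0.10, and BMPR1B, a receptor for bone morphogenetic proteins, by 0.25 ± 0.06, all members of the granulosa identity list (median 0.001, camera adjusted p = 0.806), in which AMH and INHBB fell. ID2, a target of those receptors, rose (0.54 ± 0.10), while SMAD4, their shared signal carrier, fell (-0.34 ± 0.06), and the TGF-beta and BMP list as a whole stayed near 0 (median 0.02, mean -0.02, camera adjusted p = 0.758). In the oxidative stress list NFE2L2, a regulator of antioxidant genes, rose by 0.27, and the peroxidase GPX4 (-0.28) and GCLM, a subunit of the enzyme that starts glutathione synthesis (-0.29), fell. SPARC, a matrix protein (0.25 ± 0.05), and APOA1, of the hepatocyte list kept as a negative check (0.37 ± 0.07), rose as well.

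The sows differed in how far they followed the common size effect. The correlation of a sow's size effect with the mean of the other 7 was 0.64 in H2124, 0.633 in L2673, 0.562 in H2279, 0.52 in L1808, 0.479 in L2633, 0.356 in H2723, 0.324 in H2684 and 0.0922 in L2434.

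It was asked whether the size response grows with the size range of the sow, which predicts a larger projection on the common effect in HighVAR sows. Each sow's size effect was projected on the mean of the other sows. The mean was 0.778 (SD 0.419) in 4 HighVAR and 0.771 (SD 0.467) in 4 LowVAR sows, with an exact p of 1 over the 70 assignments. With 4 sows per group the test cannot tell a small difference from none.

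Of the 35 splits of the 8 sows, 1 gave 815 features past the threshold, while the next gave 22 and 33 gave 0. It set H2124, H2684, L1808 and L2633 against H2279, H2723, L2434 and L2673, with 2 HighVAR and 2 HighCOC sows on each side. The mean log2 Cy5 signal was 11.656 ± 0.404 (SD, 4 sows) on the first side and 12.195 ± 0.638 on the other, and the detected share 39.6% and 43.3%. With slide as a fixed term and sow as a random block 1813 features passed. That fit took each array as a value, although the split lies between sows. Of the 11 slides 5 held 2 sows of each side and 6 held 3 of one side.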
